A study of Caenorhabditis elegans with 12 samples.

How the data were processed

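The data were 12 RNA sequencing libraries of whole hermaphrodite worms at 5 days, 3 from each of the strains N2, MIR73, MIR75 and MIR77. The labels state total RNA and the Illumina TruSeq RNA v2 kit. Per the submitters' processing notes, the tools used on the reads before the count table was deposited were bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4, with genome build WBcel235. The settings of each tool, the annotation release and the strand setting are not given in the sources used here. The count table as deposited holds whole numbers for 46748 genes, with 27.4 to 39.1 M counts per library. The RPKM table was deposited by the authors beside the counts, and its calculation is not given in the sources used here. The ratio of count to RPKM is fitted by 1 factor per gene and 36 factors recycled down the table, with a residual SD of 0.0028 on the natural log scale, against 0.153 with 1 factor per sample. The RPKM values are therefore scaled to gene length but not to the depth of each sample, and they served only as an alternative. Replicates were numbered in the order of the sample records, because the labels carry no replicate numbers. The records of N2, MIR73 and MIR77 alternate, and the deviations of same-numbered libraries from their strain means correlated at 0.12 to 0.219 in all 3 pairs of N2 and MIR73, against at most 0.013 in the 6 other pairs of these strains. The order of the records was therefore taken as a possible pairing for MIR73 against N2, on the evidence of the counts and not of the labels, and that comparison was also fitted with a replicate block. The labels name no batches. The 3 MIR75 records are consecutive, so a difference in the handling of those libraries would coincide with the strain.

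Counts were analysed in R 4.3.3. Of 26159 genes with a count, 14461 passed the filter of edgeR (filterByExpr with the strain as group) and were tested, 13866 of them with a gene symbol and 14360 with a position. A single edgeR 4.0.16 quasi-likelihood fit of all 12 libraries with TMM factors, at 0.959 to 1.02, gave all 5 comparisons, so that the strains share 1 estimate of the spread. The common biological coefficient of variation was 0.0687. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Log2 changes are those of the fit. Their standard errors (SE) were derived from its test, as the size of the change divided by the square root of the F statistic. CPM values are means with the SD over 3 libraries. Shares of ribosomal RNA, at 0.806% to 1.78% of counts, and of mitochondrial genes, at 0.384% to 0.584%, were computed per library. Principal components were taken from the log CPM of the tested genes.

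The 33 gene lists, covering pathways, gene families and cell type markers, were written from general knowledge before the data were examined. Of these, 1 had no tested gene, and 13 names in the lists matched no gene of the table. Each of the 32 lists left was tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, and again with a correlation estimated per list, with adjustment over the 32 lists. Beside the calls adjusted over all tested genes, calls adjusted over the members of the list alone were counted. Groups that mixed strains also gave many list calls with the preset correlation, so a call with it alone is weak evidence.

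The rule for the genes named was also fixed beforehand. It took prdh-1 and alh-13, the 6 largest rises and 6 largest falls in each comparison with N2, and up to 4 members of each list with the smallest p. In the direct comparisons it took 4 rises and 4 falls, and for genes changed in all 3 strains 5 of each. The rises and falls in single comparisons had an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the libraries of the strains. Those in all 3 strains needed only an adjusted p under 0.05 in each and were those with the smallest maximum of their adjusted p. Some genes of the rule were left out of the text. The segments of chromosome II were found after the values had been seen. They are runs of at least 50 windows of 25 neighbouring tested genes whose median log2 change lies above 0.3. For comparison, as many MIR75 log2 changes as chromosome II holds were drawn at random from all tested genes, 1000 times. Only the highest running median of each draw was kept.

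Overlaps of calls between strains were set beside 20 simulations of unchanged strains and beside the product of the numbers of calls divided by the genes tested. Each simulation drew the counts of all 12 libraries, N2 included, from gene means over all strains. Each comparison was repeated on every other split of its libraries into groups of the same sizes. Genes with at least 10 counts over all libraries that were not tested and overlap no tested gene were compared between the segments and the rest of chromosome II. Intervals of list medians came from 2000 bootstrap draws of genes.

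The pipeline was tested on simulated data with the means, depths and spread of the libraries. Of 100 genes planted at 2-fold, edgeR recovered 90, and of 100 at 1.5-fold, 67. It also called 14 unchanged genes, 0.0982% of all unchanged genes. DESeq2 1.42.0 recovered 89 and 68 with 19 unchanged genes called, and limma-trend 88 and 66 with 12. With each of these tools, unchanged genes made up a larger share of the calls than the threshold on the adjusted p allows on average. The calls in the real comparisons may therefore hold more false ones than that threshold states. The segment scan recovered 99 of 100 genes planted at 1.5-fold as 1 segment and found 0 segments where none was planted.

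The alternatives tried were the size factors of DESeq2 in the edgeR fit, the DESeq2 Wald test, no low-count filter, a fit of only the strains compared, the estimated correlation for lists, the deposited RPKM with limma-trend and pseudocounts of 0.1 and 1, and leaving out each library in turn. The DESeq2 test was run on all 26159 genes with a count and with its own filter. It therefore differs from the main fit in the genes entered as well as in the test. RPKM recomputed from the counts with the depth of each library, counts without the genes of the 2 segments, a replicate block by record order in N2, MIR73 and MIR77, the same block in N2 and MIR73 alone, and the counts of the fatty acid list by kind of gene, were chosen after seeing the data. Reads were not realigned, so transcript isoforms, the GFP sequence and genomic copies were not analysed here.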

Results

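Gene expression was measured by RNA sequencing in whole hermaphrodite Caenorhabditis elegans at 5 days of age. The 12 libraries came from 4 strains with 3 libraries each. N2 was the wild-type strain, MIR73 and MIR75 both carried a GFP fusion of B0513.5, and MIR77 carried a GFP fusion of T22H6.2. The series title calls the transgenic worms overexpression mutants. B0513.5 is prdh-1, which encodes proline dehydrogenase, the enzyme that begins proline breakdown. T22H6.2 is alh-13, which encodes the enzyme that makes the proline precursor pyrroline-5-carboxylate from glutamate. Reads counted to genes, in M, totalled 27.9, 31.7 and 27.4 M in N2, 29.8, 38.3 and 39.1 M in MIR73, 30.6, 33.4 and 27.5 M in MIR75, and 30.9, 28.4 and 34.8 M in MIR77. Of 46748 genes in the table, 14461 had enough counts to be tested. The labels do not say whether the libraries of a strain came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

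The libraries grouped by strain. The first principal component held 40.3% of the variance and ran from MIR77, at -36.7 to -24.5, to MIR73, at 35.7 to 40.4. The second held 19.9% and set MIR75, at 19.5 to 38.4, apart from the libraries of the other strains, at -17.6 to -3.23. MIR75 replicate 2 lay nearest to the other strains. Its counts also differed most from those of its own replicates. The chi-square of the counts against sampling noise, per degree of freedom, was 19.6 and 16.7 in its pairs with MIR75 replicates 1 and 3. In every other pair of replicates of a strain it was 3.37 to 9.55. Vitellogenin transcripts, which encode the yolk proteins, took 3.19% ± 0.25 of the counts in N2 (SD, n = 3), 2.32% ± 0.18 in MIR73, 3.69% ± 0.42 in MIR75 and 4.25% ± 0.28 in MIR77.

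The strains were first compared for the genes named in their fusions. The level of alh-13 (WBGene00011938, chromosome X, 12782394 to 12787147, build WBcel235) was 13.6 ± 0.043 counts per M (CPM) in N2 (SD, n = 3) and 94.3 ± 16 in MIR77. This was a 6.92-fold rise, with a log2 change of 2.79 ± 0.21 (SE, edgeR adjusted p = 3.5e-06), and every MIR77 library lay above every library of the other strains. The level of prdh-1 (WBGene00007197, chromosome IV, 13868556 to 13876615) was 13.6 ± 0.67 CPM in N2 and 20.5 ± 3.2 in MIR75, a 1.5-fold rise (log2 change 0.59 ± 0.11, edgeR adjusted p = 0.0020). In MIR73, which carries the same fusion, prdh-1 was at 17.3 ± 1.4 CPM, above N2 in all 3 libraries, but the change of 0.34 ± 0.11 did not pass the threshold (adjusted p = 0.076). It passed when only the strains compared were fitted (adjusted p = 0.042). The difference in prdh-1 between MIR75 and MIR73 was 0.24 ± 0.10 (adjusted p = 0.12). In MIR77 prdh-1 was at 14.4 ± 0.90 CPM, with a log2 change of 0.08 (adjusted p = 0.61). The level of alh-13 was 19.1 ± 2.2 CPM in MIR73 (adjusted p = 0.28, but 0.0098 when only the strains compared were fitted) and 18.6 ± 8.2 in MIR75 (adjusted p = 0.26), where its libraries were at 13.3, 28.0 and 14.5 CPM. Reads of a fusion transgene and of the endogenous gene were not told apart in these counts.

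Among 4 genes often used to mark transgenic worms, unc-119, a trafficking protein of neurons whose rescue serves as a selection marker, rose in all 3 strains. It was at 18.4 ± 2.1 CPM in N2 (WBGene00006843, chromosome III, 10902641 to 10908935), 115 ± 17 in MIR73, 70.7 ± 8.9 in MIR75 and 430 ± 52 in MIR77. The log2 changes were 2.65 ± 0.13 (edgeR adjusted p = 1.1e-09), 1.95 ± 0.13 (1.1e-07) and 4.55 ± 0.13 (4.8e-11). Of the other markers, the collagen gene rol-6 (log2 change 1.53, adjusted p = 0.023) and the pharyngeal myosin gene myo-2 (0.52, adjusted p = 0.036) passed the threshold in MIR77. Both missed it without N2 replicate 2 (adjusted p = 0.085 and 0.12), N2 replicate 3 (0.052 and 0.11) or MIR77 replicate 1 (0.10 and 0.12). The gene myo-2 also missed it without MIR77 replicate 2 (adjusted p = 0.15), and rol-6 with the DESeq2 test (adjusted p = 0.12). The list of 4 was called higher in MIR73 (1 rose and 0 fell, 1 and 2 when adjusted over the list alone; camera adjusted p = 0.024), in MIR75 (1 and 0, 1 and 1 when adjusted over the list alone; 0.024) and in MIR77 (3 and 0, likewise when adjusted over the list alone; 6.8e-13). With an estimated correlation the adjusted p was 0.44, 0.41 and 0.029. In MIR73 the median of the list was -0.28, against a mean of 0.00 and a test direction upward.

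**Figure D1:**
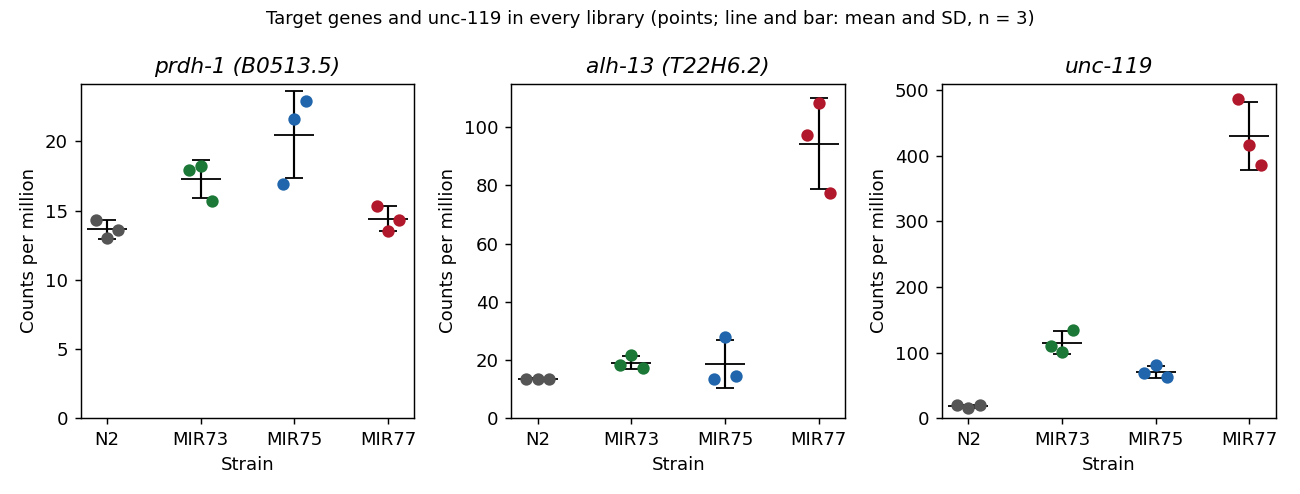
Counts per M of prdh-1, alh-13 and unc-119 by strain, with 1 point per library and the mean and SD over 3 libraries. The MIR77 libraries lie at 77.3 to 108 for alh-13, and unc-119 lies at 63.1 or more in every transgenic library against at most 19.7 in N2.

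MIR73 was compared with N2 for the transcripts that differ in worms with the prdh-1 fusion. Antimicrobial effectors, infection response genes and C-type lectins were called lower as lists in MIR73, with 20 of 55, 8 of 15 and 28 of 110 genes lower. Cuticle collagens and intestine markers, with 43 of 123 and 6 of 14 genes lower, were called too, but not with an estimated correlation (adjusted p = 0.56 and adjusted p = 0.44). The C-type lectins lost their call with an estimated correlation and a replicate block together (camera adjusted p = 0.12). The lysozyme gene lys-7 was at 2160 ± 42 CPM in N2 (SD, n = 3) and 480 ± 25 in MIR73, 4.50-fold lower (log2 change -2.17 ± 0.06, edgeR adjusted p = 5.2e-12). The saposin-like antimicrobial gene spp-5 fell from 389 ± 11 to 99.3 ± 5.8 CPM and the intestinal esterase gene ges-1 from 32.9 ± 1.2 to 11.9 ± 0.11 CPM. In all, 183 genes were higher and 729 lower in MIR73, of which 28 and 401 differed at least 2-fold.

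Of 55 tested antimicrobial effector genes, 20 fell and 0 rose in MIR73 (26 and 3 when adjusted over the list alone), with a median log2 change of -0.63 (camera adjusted p = 9.4e-37, and adjusted p = 0.0032 with an estimated correlation). The saposin-like gene spp-2 changed by -1.95 ± 0.07 (edgeR adjusted p = 4.7e-11). Of 110 tested C-type lectin genes, which encode sugar-binding proteins, 28 fell and 2 rose (39 and 4 when adjusted over the list alone; camera adjusted p = 3.3e-10, and adjusted p = 0.034 with an estimated correlation, but adjusted p = 0.12 with an estimated correlation and a replicate block). Among them clec-50 fell from 251 ± 4.7 to 68.4 ± 2.5 CPM and clec-62 from 56.4 ± 3.8 to 13.7 ± 0.91 CPM. Of 15 infection response genes, 8 fell and 0 rose (8 and 1 when adjusted over the list alone; camera adjusted p = 3.1e-09, and adjusted p = 0.0032 with an estimated correlation), including irg-3 at -1.53 ± 0.10 and irg-7 at -0.69 ± 0.05. Of 7 genes known to be lowered by the longevity factor DAF-16, 3 fell and 0 rose, likewise when adjusted over the list alone (camera adjusted p = 1.0e-06, and adjusted p = 0.0069 with an estimated correlation). These were dod-24 (-1.30 ± 0.17), dod-23 (-1.17 ± 0.05) and dod-19 (-1.09 ± 0.10). The list shares 2 tested genes with the infection response list.

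Of 123 tested cuticle collagen genes, 43 fell and 2 rose in MIR73 (66 and 8 when adjusted over the list alone), with a median log2 change of -1.01. The list was called lower (camera adjusted p = 1.6e-08), but not with an estimated correlation (adjusted p = 0.56). Of its members, col-144 was at 2.94 ± 1.1 CPM in N2 and 0.421 ± 0.067 in MIR73, and col-125 at 7.05 ± 2.6 and 1.03 ± 0.23. Of 14 intestine markers, 6 fell and 0 rose, likewise when adjusted over the list alone (camera adjusted p = 4.1e-05, but adjusted p = 0.44 with an estimated correlation), among them the aspartic protease gene asp-1 (-1.12 ± 0.12). The yolk protein genes vit-5 (-0.70 ± 0.06) and vit-6 (-0.63 ± 0.08) fell and vit-1 (0.80 ± 0.12) rose. Of the 6 vitellogenins 1 rose and 2 fell (2 and 2 when adjusted over the list alone), and the list was not called (adjusted p = 0.19). The eggshell genes perm-2 (-0.92 ± 0.07) and perm-4 (-0.74 ± 0.06) were the 2 that fell among 36 oocyte and germ line markers, where 0 rose, likewise when adjusted over the list alone, and the list was not called (adjusted p = 0.19). Ribosomal protein genes were called slightly higher as a list of 80 (median 0.08; 1 rose and 0 fell, 0 and 0 when adjusted over the list alone; camera adjusted p = 4.3e-06, but adjusted p = 0.64 with an estimated correlation). Lysosomal lipases were not called in the main fit (1 rose and 2 fell of 7, likewise when adjusted over the list alone, camera adjusted p = 0.12). Nor were genes of the propionate shunt and methionine cycle (3 and 0 of 19, likewise when adjusted over the list alone, camera adjusted p = 0.089). With the replicate block these lists were called, lower and higher (camera adjusted p = 0.020 and adjusted p = 0.039). With an estimated correlation they were not called even then (adjusted p = 0.31 and adjusted p = 0.41).

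Among genes with a mean of at least 5 CPM, the 2 largest falls in MIR73 lay near the left end of chromosome II. The gene rfip-2, a homologue of Rab11-interacting proteins (723788 to 732513), fell 29.8-fold from 116 ± 4.3 to 3.85 ± 1.5 CPM, and 2L52.1 (1848 to 5514) fell 21.7-fold from 15.7 ± 2.1 to 0.720 ± 0.011 CPM. Other large falls were in F42A10.6 (-2.57 ± 0.17) and C53B7.2 (-2.56 ± 0.10). The largest rises after unc-119, under the same limit of 5 CPM, were in pud-3 (4.59-fold, to 9.13 ± 2.5 CPM), scb-1 (1.43 ± 0.10) and pud-4 (1.36 ± 0.15). The pud genes were named for proteins more abundant in insulin receptor mutants. Reads of F42A10.6, col-125 and scb-1 were not told apart from those of overlapping genes on the opposite strand. The number of genes higher in MIR73 moved from 183 to 102 without N2 replicate 3, 108 without MIR73 replicate 1 and 95 without MIR73 replicate 2. On the deposited RPKM values, whose divisor does not follow the depth of each library, 98 genes were higher and 201 lower with a pseudocount of 1.

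**Figure D2:**
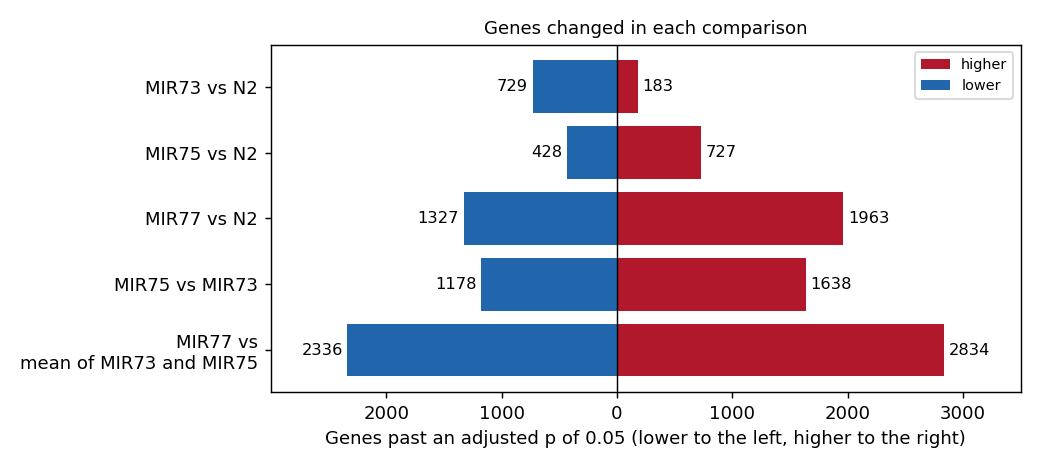
Number of genes past an adjusted p of 0.05 in each of the 5 comparisons, with genes lower drawn to the left of 0 and genes higher to the right. MIR73 against N2 holds mostly genes lower, 729 against 183 higher, and the comparison of MIR77 with the mean of MIR73 and MIR75 holds the most genes.

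MIR75 carries a fusion of the same gene as MIR73 and was compared with N2 in the same way. Infection response genes were higher in MIR75 in 10 of 15 cases, and genes in 2 segments of chromosome II in 192 of 238. Of 7 lysosomal lipase genes, 4 were lower. The lectin gene clec-174 rose 36.5-fold, from 0.625 ± 0.34 CPM in N2 (SD, n = 3) to 22.8 ± 3.5 in MIR75 (log2 change 5.19 ± 0.24, edgeR adjusted p = 3.0e-09). The infection response gene irg-7 was at 340 ± 30 CPM in N2 and 607 ± 17 in MIR75, and the lysosomal lipase gene lipl-1 fell from 25.1 ± 2.4 to 7.21 ± 1.7 CPM. In all, 727 genes were higher and 428 lower in MIR75, of which 162 and 106 differed at least 2-fold.

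A running median of the log2 change over 25 neighbouring genes found 2 segments of raised expression in MIR75, both on chromosome II. The segment from 4689777 to 5255535 held 100 tested genes, of which 80 were higher and 0 lower, with a median log2 change of 0.67. The segment from 6283384 to 7012692 held 138 tested genes, of which 112 were higher and 0 lower, with a median of 0.77. Together they held 26.4% of all genes higher in MIR75. The 50 tested genes on either side of each segment had medians of -0.01, -0.01, -0.03 and 0.02. In MIR73 the medians of the segments were -0.01 and -0.03, and in MIR77 -0.02 and 0.05. The highest running median was 0.89, against at most 0.26 in 1000 random draws of log2 changes from the tested genes of all chromosomes. Genes of the segments included the superoxide dismutase gene sod-1 (155 ± 6.8 CPM in N2, 257 ± 6.2 in MIR75), the glutathione S-transferase gene gst-7 (204 ± 14 and 364 ± 11), the autophagy genes lgg-1 (396 ± 13 and 669 ± 13), epg-5 (0.76 ± 0.06) and atg-16.2 (0.91 ± 0.07), the intestinal acid phosphatase gene pho-1 (1.58 ± 0.13), the synaptotagmin gene snt-1 (1.05 ± 0.13) and the synaptic vesicle kinesin gene unc-104 (0.86 ± 0.08).

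**Figure D3:**
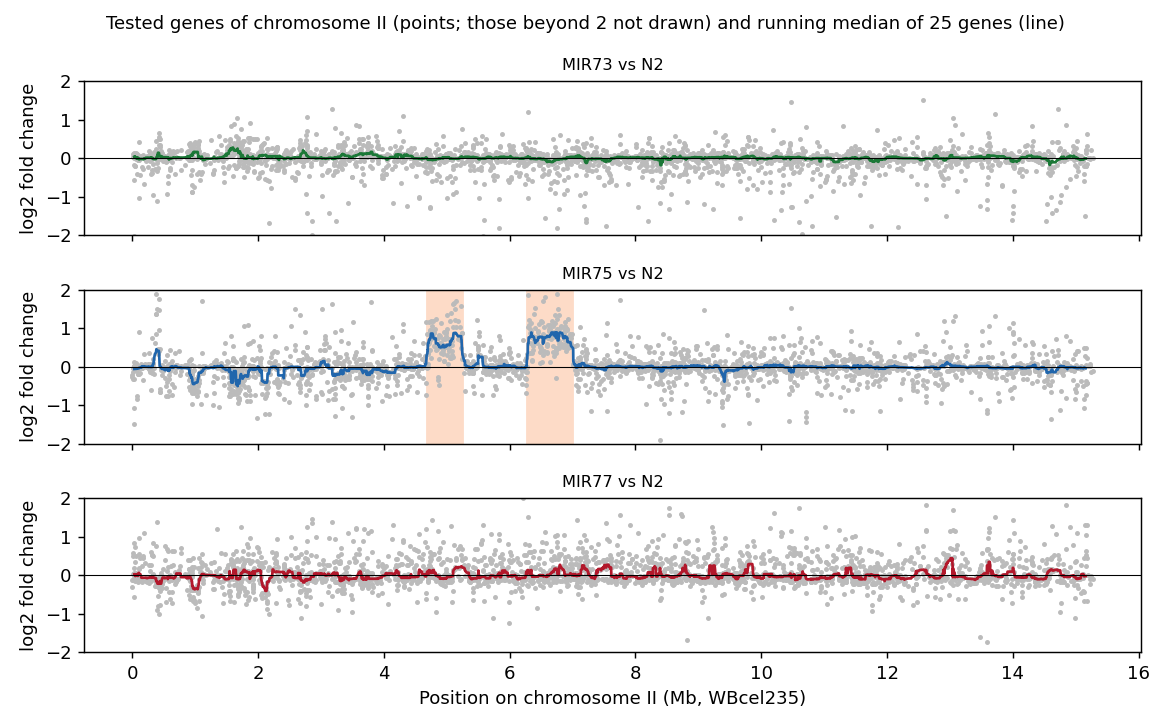
Log2 change against N2 of the tested genes along chromosome II in build WBcel235 (grey points, those beyond 2 in either direction not drawn) and the running median over 25 genes (line) in MIR73, MIR75 and MIR77. The shaded segments in MIR75, from 4689777 to 5255535 and from 6283384 to 7012692, have medians of 0.67 and 0.77 and lie near 0 in the other strains.

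Of the 15 infection response genes, 10 rose and 0 fell in MIR75 (12 and 2 when adjusted over the list alone), with a median log2 change of 0.91 (camera adjusted p = 3.0e-17, and adjusted p = 0.00041 with an estimated correlation). They included irg-8 (0.99 ± 0.08), sysm-1 (1.47 ± 0.17) and dod-24, which rose from 43.3 ± 5.0 to 176 ± 30 CPM. Of the 7 genes lowered by DAF-16, 5 rose and 1 fell, likewise when adjusted over the list alone (camera adjusted p = 0.024, but adjusted p = 0.21 with an estimated correlation); dod-22 changed by 2.65 ± 0.33, dod-17 by 1.75 ± 0.17 and dod-23 by -1.90 ± 0.06. Of 7 lysosomal lipase genes, 4 fell and 0 rose (5 and 0 when adjusted over the list alone; camera adjusted p = 1.6e-10, and adjusted p = 0.015 with an estimated correlation), with lipl-2 at -1.78 ± 0.18 and lipl-5 at -1.13 ± 0.08. Antimicrobial effectors went both ways, with 7 that rose and 12 that fell of 55 (9 and 15 when adjusted over the list alone; camera adjusted p = 0.0010 downward, but adjusted p = 0.38 with an estimated correlation). Of these, spp-1 fell from 63.3 ± 11 to 15.8 ± 1.7 CPM and spp-5 from 389 ± 11 to 212 ± 13 CPM. Of 110 C-type lectins, 19 rose and 15 fell (19 and 20 when adjusted over the list alone), and the list was not called (adjusted p = 0.73). The lectin gene clec-166 changed by -2.11 ± 0.13. Cuticle collagens were lower, with 21 that fell, such as col-124 (-1.30 ± 0.10), and 3 that rose of 123 (28 and 4 when adjusted over the list alone; camera adjusted p = 4.2e-06, but adjusted p = 0.62 with an estimated correlation).

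Of 36 genes of fatty acid desaturation, elongation and activation, 8 fell and 1 rose in MIR75 (10 and 2 when adjusted over the list alone). Of the 8 that fell, 7 were desaturase and elongase genes, among them the stearoyl-CoA desaturase genes fat-7 (-0.76 ± 0.08) and fat-6 (-0.42 ± 0.05). The list was not called (camera adjusted p = 0.16). Without the genes of the 2 segments, its 35 remaining genes were called lower with the preset correlation (camera adjusted p = 0.0092). The antioxidant list (4 rose and 1 fell of 24, likewise when adjusted over the list alone; camera adjusted p = 0.024, but adjusted p = 0.27 with an estimated correlation), the SKN-1 target list (3 and 0 of 15, likewise when adjusted over the list alone; 0.0070, but adjusted p = 0.21 with an estimated correlation) and the autophagy list (3 and 0 of 28, likewise when adjusted over the list alone; 0.039, but adjusted p = 0.62 with an estimated correlation) were called higher. The median of the autophagy list was -0.02, its mean 0.06 and its test upward. Without the genes of the 2 segments these lists had adjusted p of 0.15, 0.14 and 0.59. Neuron markers were called higher (3 rose and 0 fell of 18, 6 and 0 when adjusted over the list alone; 0.0017, but adjusted p = 0.62 with an estimated correlation), as were cytosolic heat shock proteins (3 and 0 of 9, 5 and 0 when adjusted over the list alone; 0.0074, but adjusted p = 0.21 with an estimated correlation) and ribosomal proteins (2 and 0 of 80, likewise when adjusted over the list alone; 0.00060, but adjusted p = 0.83 with an estimated correlation). The cytochrome P450 family was called lower (3 rose and 10 fell of 66, 3 and 14 when adjusted over the list alone; 0.017, but adjusted p = 0.41 with an estimated correlation), with cyp-14A3 at -2.06 ± 0.33.

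Outside these groups, the largest rises in MIR75 at a mean of at least 5 CPM were in pud-4 (3.04 ± 0.14), pud-3 (2.59 ± 0.25), the solute carrier gene slc-17.9 (2.13 ± 0.14) and the proton-coupled inositol transporter gene hmit-1.1 (2.12 ± 0.14). Reads of spp-1, col-124, epg-5 and pho-1 were not told apart from those of overlapping genes on the opposite strand. The number of genes lower in MIR75 moved from 428 to 303 without MIR75 replicate 1, 608 without MIR75 replicate 2 and 257 without MIR75 replicate 3. With RPKM recomputed from the counts and scaled to the library totals, 605 genes were higher and 772 lower.

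MIR77 was compared with N2 for the transcripts that differ in worms with the alh-13 fusion. Antimicrobial effectors and a list of genes of fatty acid desaturation, elongation and activation were called higher in MIR77, with 30 of 55 and 11 of 36 genes higher. Of these 11, 8 encode acyl-CoA synthetases. Muscle markers (17 of 18), vitellogenins (6 of 6), cuticle collagens (51 of 123), glutathione S-transferases (18 of 35) and UDP-glucuronosyltransferases (23 of 60) were called higher too. With an estimated correlation these were not called (adjusted p = 0.15, adjusted p = 0.15, adjusted p = 0.34, adjusted p = 0.068 and adjusted p = 0.20). The muscle troponin I gene unc-27 rose from 92.9 ± 3.8 CPM in N2 (SD, n = 3) to 151 ± 3.2 in MIR77, a 1.63-fold rise (log2 change 0.70 ± 0.07, edgeR adjusted p = 1.8e-05). The epidermal antimicrobial peptide gene nlp-29 changed by 1.37 ± 0.12. The glutathione S-transferase gene gst-4, a standard reporter of the stress factor SKN-1, rose from 3.75 ± 1.0 to 12.5 ± 0.16 CPM. In all, 1963 genes were higher and 1327 lower in MIR77, of which 350 and 53 differed at least 2-fold.

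Of 55 antimicrobial effector genes, 30 rose and 1 fell in MIR77 (32 and 1 when adjusted over the list alone), with a median log2 change of 0.59 (camera adjusted p = 2.1e-15, and adjusted p = 0.035 with an estimated correlation). The caenacin genes cnc-4 (1.59 ± 0.11) and cnc-2 (1.45 ± 0.17) were among them. Of 110 C-type lectins, 27 rose and 1 fell (29 and 2 when adjusted over the list alone; camera adjusted p = 0.00069, but adjusted p = 0.20 with an estimated correlation), including clec-62 (0.58 ± 0.07) and clec-48 (0.74 ± 0.09). Of 123 cuticle collagens, 51 rose and 7 fell (54 and 8 when adjusted over the list alone), with a median of 0.73 (camera adjusted p = 1.6e-12, but adjusted p = 0.34 with an estimated correlation). Examples were col-181, at 273 ± 29 CPM in N2 and 472 ± 20 in MIR77, and col-98, at 17.8 ± 1.1 and 49.8 ± 8.3. Of 18 muscle markers, 17 rose and 0 fell, likewise when adjusted over the list alone, with a median of 0.59 (camera adjusted p = 1.1e-18, but adjusted p = 0.15 with an estimated correlation). The myosin light chain gene mlc-3 changed by 0.66 ± 0.08 and the troponin C gene pat-10 by 0.61 ± 0.08.

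Glutathione S-transferases, which attach glutathione to reactive compounds, rose in 18 of 35 tested genes and fell in 0, likewise when adjusted over the list alone (camera adjusted p = 7.0e-07, but adjusted p = 0.068 with an estimated correlation), with gst-10 at 1.05 ± 0.17 and gst-13 at 0.66 ± 0.08. Of 60 UDP-glucuronosyltransferases, 23 rose and 0 fell (25 and 0 when adjusted over the list alone; 9.7e-07, but adjusted p = 0.20 with an estimated correlation), with ugt-44 at 0.68 ± 0.08 and ugt-32 at 1.95 ± 0.29. Of 15 SKN-1 targets, 9 of them members of the glutathione S-transferase list, 7 rose and 0 fell, likewise when adjusted over the list alone (0.00018, but adjusted p = 0.068 with an estimated correlation). All 6 vitellogenins rose, likewise when adjusted over the list alone (9.7e-07, but adjusted p = 0.15 with an estimated correlation); vit-2 changed by 0.51 ± 0.09 and vit-4 by 0.81 ± 0.12. Of 36 genes of fatty acid desaturation, elongation and activation, 11 rose and 1 fell (15 and 1 when adjusted over the list alone; 0.00086, and adjusted p = 0.035 with an estimated correlation). Of its 18 acyl-CoA synthetase genes 8 rose and 0 fell, and of its 15 desaturase and elongase genes 3 rose and 1 fell, with fat-7 at 0.91 ± 0.08 and the elongase gene elo-6 at 0.58 ± 0.11. Of 40 genes of fatty acid oxidation, 10 rose and 1 fell (11 and 1 when adjusted over the list alone; 0.040, but adjusted p = 0.25 with an estimated correlation), including the acyl-CoA oxidase gene acox-1.5 (0.75 ± 0.07), the acyl-CoA dehydrogenase gene acdh-1 (0.82 ± 0.12) and hacd-1 (0.75 ± 0.09), which encodes a hydroxyacyl-CoA dehydrogenase.

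Of 14 tested genes of proline and glutamate metabolism, 5 rose and 1 fell in MIR77 (6 and 2 when adjusted over the list alone; camera adjusted p = 0.022, but adjusted p = 0.38 with an estimated correlation). Besides alh-13, they included the glutaminase gene glna-2 (0.49 ± 0.09) and the glutamine synthetase gene gln-3 (0.40 ± 0.08). The list was not tested without alh-13, the gene of the fusion, so its call is not independent of the transgene. The same list was not called in MIR73 (3 rose and 1 fell, 5 and 1 when adjusted over the list alone; adjusted p = 0.16) or in MIR75 (1 and 0, 2 and 0 when adjusted over the list alone; adjusted p = 0.39). Intestine markers (9 rose and 1 fell of 14, likewise when adjusted over the list alone; 0.00048, but adjusted p = 0.34 with an estimated correlation) and neuron markers (7 and 0 of 18, 8 and 0 when adjusted over the list alone; 0.0022, but adjusted p = 0.40 with an estimated correlation) were called higher, with asp-1 at 0.74 ± 0.12, the proton pump gene vha-6 at 0.41 ± 0.08 and the synaptic gene unc-13 at 0.56 ± 0.11. Oocyte and germ line markers were called lower (camera adjusted p = 0.0021, but adjusted p = 0.57 with an estimated correlation). Of 36, 2 rose and 6 fell (2 and 9 when adjusted over the list alone). Histone genes were called lower too (camera adjusted p = 0.010, but adjusted p = 0.40 with an estimated correlation). This list took every gene named his-, 72 in all, of which 24 were tested. Of the 24, 1 rose and 6 fell, likewise when adjusted over the list alone, with his-60 at -0.59 ± 0.11. Autophagy genes were also called lower (camera adjusted p = 0.011, but adjusted p = 0.38 with an estimated correlation). Of 28, 0 rose and 4 fell (0 and 0 when adjusted over the list alone). Ribosomal proteins were called lower with a median of -0.03, although 1 of the 80 rose and 0 fell (0 and 0 when adjusted over the list alone; 0.028, but adjusted p = 0.73 with an estimated correlation).

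**Figure D4:**
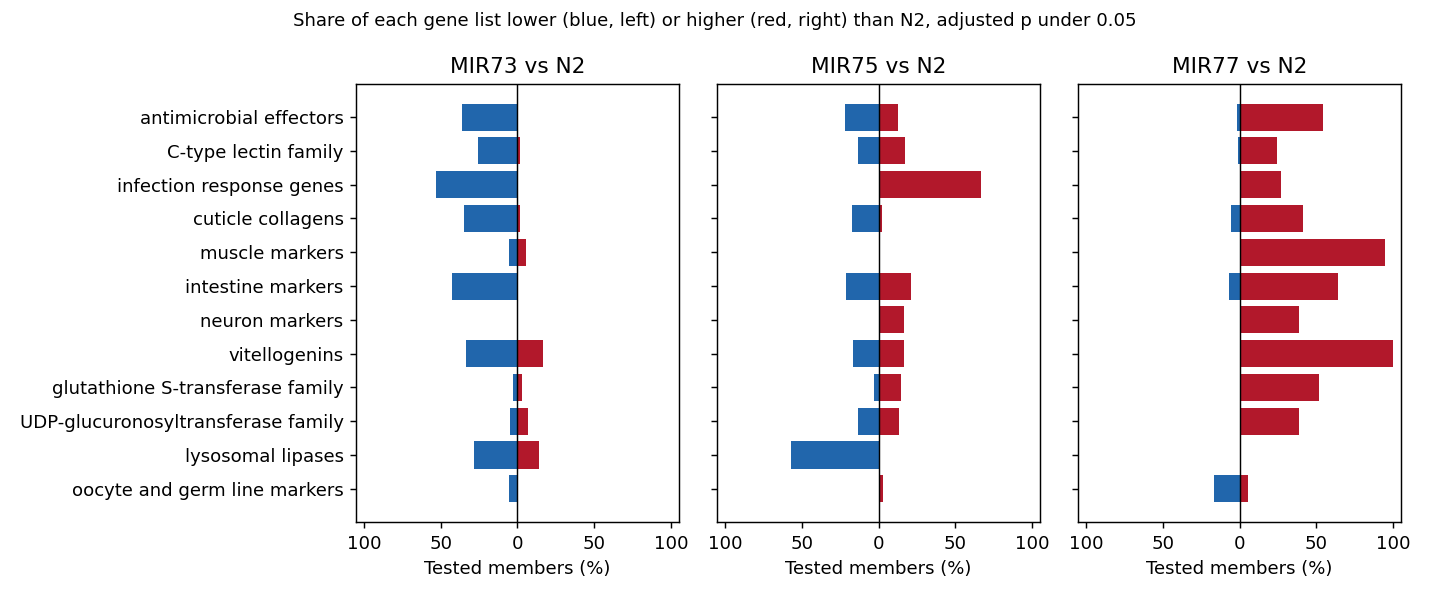
Share of the tested members of 12 gene lists that were lower (left of 0) or higher (right of 0) than N2 in each transgenic strain, in percent. Antimicrobial effectors and cuticle collagens lie on the lower side in MIR73 (20 of 55 and 43 of 123 members) and on the higher side in MIR77 (30 of 55 and 51 of 123 members).

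Outside these groups, the largest rises in MIR77 after unc-119 and alh-13, at a mean of at least 5 CPM, were in aex-5, Y37H2A.13, ora-1 and F57H12.6. The level of aex-5, a proprotein convertase gene of the defecation cycle, went from 5.86 ± 0.75 CPM in N2 to 28.9 ± 2.3 in MIR77. Y37H2A.13 went from 6.23 ± 1.1 to 30.6 ± 4.6 CPM, and the neighbouring genes ora-1 and F57H12.6 from 7.54 ± 4.2 to 36.3 ± 8.0 and from 7.98 ± 7.1 to 36.6 ± 14 CPM. The largest falls included B0511.11 (-2.39 ± 0.25), F46C5.1 (-1.70 ± 0.24) and the homeobox gene mls-2 (-1.14 ± 0.24). Reads of gst-4 and aex-5 were not told apart from those of overlapping genes, and those of near-identical family members such as the vitellogenins and histones may be split between copies. The counts of 1963 genes higher and 1327 lower moved to 1226 and 650 without N2 replicate 2, 997 and 338 without N2 replicate 3, 1129 and 317 without MIR77 replicate 1, and 999 and 322 without MIR77 replicate 2. On the deposited RPKM values with a pseudocount of 0.1, 589 genes were higher and 35 lower.

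The strains were also compared for genes changed against N2 in the same direction. In all 3 strains 29 genes rose and 31 fell, where independent lists would share 1.25 and 1.98. The 20 simulations, whose comparisons shared simulated and not observed N2 libraries, gave 0 shared genes. The simulated strains were unchanged and so had few calls to share. They do not show how many genes strains with unrelated changes would share through the N2 libraries. Genes that rose in all 3 included unc-119, pud-3, the neprilysin peptidase gene nep-22 (log2 changes of 0.75, 0.86 and 0.94 in MIR73, MIR75 and MIR77), the triglyceride synthesis gene dgat-2 (0.66, 1.01 and 1.01) and aex-5 (0.63 and 0.72 in MIR73 and MIR75). Genes that fell in all 3 included dod-23 (-1.17, -1.90 and -0.65), the nuclease gene nuc-1, which degrades DNA of dying cells (-0.84, -1.25 and -0.72), B0511.11 (-2.81, -2.96 and -2.39), K08D10.14 (-1.29, -2.22 and -1.30, at a mean of 3.14 CPM) and tag-344 (-3.48, -3.22 and -3.17, at 0.716 CPM).

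MIR73 and MIR75, with fusions of the same gene, shared 34 genes that rose and 118 that fell, while 115 changed in opposite directions. Independent lists would share 9.20 and 21.6 with 42.1 in opposite directions, and the simulations shared 0.050 genes on average. The covariance of their log2 changes was 0.0227, against 0.0235 in the simulations. MIR75 and MIR77 shared 311 genes that rose and 88 that fell, with 112 in opposite directions (98.7, 39.3 and 124.8 for independent lists, 0 simulated; covariance 0.0731 against 0.0232). MIR73 and MIR77 shared 157 genes, of which 53 fell, with 335 in opposite directions. Independent lists would share 24.8 that rose and 66.9 that fell, with 116 in opposite directions, and the simulations shared 0 (covariance -0.0125 against 0.0234). Part of any excess may come from the shared N2 libraries, which are too few to be split. The number shared by MIR73 and MIR77 moved to 51.6% of its value without N2 replicate 3, 58.0% without MIR73 replicate 2 and 66.2% without MIR77 replicate 1. The number shared by MIR75 and MIR77, 399 in all, moved to 48.9% without N2 replicate 3, 64.2% without MIR77 replicate 1 and 58.9% without MIR77 replicate 2.

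The strains with fusions of prdh-1 were then compared directly. Infection response genes were higher in MIR75 than in MIR73 in 11 of 15 cases, and genes lowered by DAF-16 in 6 of 7. These lists share 2 tested genes and are not independent. The lectin gene clec-174 was at 0.213 ± 0.10 CPM in MIR73 (SD, n = 3) and 22.8 ± 3.5 in MIR75, rfip-2 at 3.85 ± 1.5 and 116 ± 5.2, and the lipase gene lips-11 at 4.52 ± 0.84 and 79.4 ± 34. The lysosomal lipase gene lipl-1 was at 36.4 ± 1.9 and 7.21 ± 1.7, col-80 at 33.0 ± 3.9 and 8.27 ± 1.5, and scb-1 at 30.2 ± 0.13 and 8.96 ± 0.77. In all, 1638 genes were higher and 1178 lower in MIR75. Infection response genes (11 higher and 0 lower of 15, 12 and 0 when adjusted over the list alone; camera adjusted p = 5.3e-23, and adjusted p = 0.00020 with an estimated correlation) and genes lowered by DAF-16 (6 and 1 of 7, likewise when adjusted over the list alone; 1.8e-07, and adjusted p = 0.0064 with an estimated correlation) were called higher. So were antimicrobial effectors (26 and 2 of 55, 27 and 2 when adjusted over the list alone; 2.0e-12, but adjusted p = 0.065 with an estimated correlation), C-type lectins (35 and 10 of 110, 37 and 12 when adjusted over the list alone; 6.3e-07, but adjusted p = 0.10 with an estimated correlation), intestine markers (9 and 0 of 14, likewise when adjusted over the list alone; 6.9e-06, but adjusted p = 0.31 with an estimated correlation) and neuron markers (8 and 0 of 18, 10 and 0 when adjusted over the list alone; 0.018, but adjusted p = 0.95 with an estimated correlation). Lysosomal lipases were called lower (0 and 3 of 7, 1 and 3 when adjusted over the list alone; 0.018, but adjusted p = 0.30 with an estimated correlation). The 1178 genes lower moved to 750 and 728 without MIR73 replicate 1 or 3 and to 735 and 619 without MIR75 replicate 1 or 3. With RPKM recomputed from the counts, 1353 genes were higher and 2681 lower, and on the deposited RPKM values with a pseudocount of 0.1, 480 and 725.

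The alh-13 strain was compared with the mean of both prdh-1 strains. Antimicrobial effectors were called higher in MIR77 as a list, with or without an estimated correlation. Cuticle collagens and muscle markers were called higher and ribosomal protein genes lower, but not with an estimated correlation (adjusted p = 0.14, adjusted p = 0.27 and adjusted p = 0.43). Cuticle collagens were higher in 92 of 123 tested genes and lower in 0 (94 and 0 when adjusted over the list alone; camera adjusted p = 2.9e-27, but adjusted p = 0.14 with an estimated correlation). Antimicrobial effectors were higher in 44 of 55 and lower in 0 (46 and 0 when adjusted over the list alone; 4.8e-47, and adjusted p = 0.0024 with an estimated correlation), and muscle markers in 17 of 18 and lower in 0, likewise when adjusted over the list alone (7.6e-11, but adjusted p = 0.27 with an estimated correlation). Ribosomal protein genes were lower in 43 of 80 and higher in 0 (53 and 0 when adjusted over the list alone), with a median log2 difference of -0.10 (4.2e-08, but adjusted p = 0.43 with an estimated correlation). Among single genes, alh-13 differed by 2.32 ± 0.17 (SE, edgeR adjusted p = 9.6e-08), F57H12.6 by 3.13 ± 0.37, clec-169 by 2.81 ± 0.24, F46C5.1 by -1.33 ± 0.22, pud-4 by -1.29 ± 0.12 and the F-box gene fbxb-88 by -0.98 ± 0.17. In all, 2834 genes were higher and 2336 lower, and 20 of 32 tested lists were called, 1 of them with an estimated correlation. The 2336 genes lower moved to 959 without MIR77 replicate 1 and 1036 without MIR77 replicate 2. On the deposited RPKM values with a pseudocount of 0.1, 922 genes were higher and 139 lower. With the DESeq2 test, which was run on all genes with a count, the balance turned over, with 2365 higher and 2567 lower.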

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

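In this part, the test of the chromosome II segments against scaling, and the tests of the collagens against the share of somatic RNA and against normalization, were chosen only after the result was seen. A first test for extra copies, the share of segment genes with a log2 change above 0 (97.9%), was largely fixed by the way the segments were chosen and decides nothing; the test below on genes outside the scan replaced it before its values were seen.

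The strains MIR73 and MIR75 carry fusions of the same gene, and their changes against N2 differed by a test of the difference itself for 2816 of 14461 tested genes (19.5%; 1638 higher and 1178 lower in MIR75) and 7 gene lists, of which 2 were called with an estimated correlation. The 61 named genes examined had been picked for their changes against N2, and some lie in the raised segments, so a larger share of them is expected to differ; 50 did, 38 with the higher value in MIR75 and 12 with the lower, at adjusted p of 0.013 or less. The differences below are log2 changes in MIR75 minus those in MIR73. Among genes of defence and of the DAF-16 regulon they were 6.72 for clec-174, 3.32 for dod-24, 2.74 for dod-22, 2.66 for sysm-1, 2.19 for lys-7, 2.16 for clec-62, 2.06 for dod-17, 1.81 for irg-3, 1.52 for irg-7, 1.44 for clec-50, 1.14 for dod-19, 1.097 for spp-5, 1.05 for irg-8, 0.89 for spp-2, -0.73 for dod-23 and -1.60 for clec-166. Among collagens they were 2.87 for col-144, 2.43 for col-125 and -1.61 for col-124. Among genes of the intestine, of lipids and of yolk or eggshell they were 1.86 for asp-1, 1.27 for pho-1, 1.096 for vit-6, 1.07 for perm-2, 0.86 for ges-1, 0.78 for perm-4, 0.74 for vit-5, 0.35 for dgat-2, -0.50 for fat-6, -1.01 for lipl-2, -1.05 for fat-7, -1.08 for vit-1 and -2.35 for lipl-1. Among genes of neurons, autophagy and oxidative stress they were 1.13 for snt-1, 0.99 for gst-7, 0.89 for atg-16.2, 0.89 for unc-104, 0.75 for epg-5, 0.72 for sod-1, 0.68 for lgg-1 and -0.70 for unc-119. For other genes they were 4.89 for rfip-2, 4.18 for 2L52.1, 2.80 for C53B7.2, 2.39 for slc-17.9, 2.24 for F42A10.6, 1.68 for pud-4, 1.33 for hmit-1.1, -0.41 for nuc-1, -0.93 for K08D10.14 and -1.75 for scb-1.

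The raised segments of chromosome II in MIR75 held 238 tested genes. A scaling difference between libraries would move the rest of the chromosome too, but the genes outside the segments had a median log2 change of -0.024. Families of related genes within the segments would leave the other genes unmoved. Genes whose family name occurs once in the segments had a median of 0.71. They are among the genes by which the segments were chosen, which favours a raised median. Relatives outside the segments were not considered, so shared reads or co-expressed families were not excluded. A single aberrant library does not account for the rise, because all 3 MIR75 libraries had a segment median above every library of the other strains. As a hypothesis, the MIR75 genome may hold extra copies of the segments; of 60 genes there with too few counts to enter the scan, 39 (65.0%, 95% interval 51.6% to 76.9%) had a higher mean in MIR75 than in N2, against 42.8% of 556 such genes on the rest of the chromosome. Any other cause that raises the whole stretch predicts this too, and no DNA sequence was analysed here.

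Cuticle collagens had a median log2 change of -1.01 in MIR73 and 0.73 in MIR77. If MIR73 worms held less somatic RNA, muscle markers would fall as far, but the collagen median minus the muscle median was -1.12 (half-widths of the 95% intervals 0.389 and 0.137). If MIR77 worms held more somatic RNA, all somatic groups would rise alike. Collagens and muscle markers did so (difference 0.14, summed half-width 0.161), as did intestine and neuron markers (0.074, 0.251). The other 4 of 6 pairs lay apart, collagens and neuron markers by 0.47 (0.195). The half-widths come from draws of genes taken as independent and hold no spread between libraries. A larger somatic share could account for part of the rise, and whether it accounts for all of it was not decided. A scaling error would move ribosomal protein genes as far, but the collagen median differed from theirs by 0.76 in MIR77 (summed half-width 0.0994) and by -1.09 in MIR73 (0.395). The test set beforehand, an exchange of TMM for DESeq2 size factors, shifted the collagen medians by -0.0064 and 0.0016 and could not tell the explanations apart, so the comparison with ribosomal proteins replaced it; stage of the worms was not tested.

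Each comparison was repeated on all splits of its libraries into groups of the same sizes, with a fit of 2 groups. With 3 libraries against 3 there are 10 splits, too few for a test at 0.05. Every other split of this kind puts libraries of both strains in each group. A strain difference then adds to the spread within the groups, so 0 genes in those splits could hardly come out otherwise and does not support the calls. The real split was the only 1 of 10 to reach its number of genes in MIR73 against N2 (882, highest other 0, as among the 4 splits that part all 3 pairs of libraries), in MIR75 against N2 (1 of 10; 799, highest other 0), in MIR77 against N2 (1 of 10; 3599, highest other 0) and in MIR75 against MIR73 (1 of 10; 1927, highest other 0). For the number of gene lists called, 7 of 10 splits reached the real 8 in MIR73 against N2 (highest other 17), 3 of them among the 4 that part all 3 pairs (highest other 8), 1 of 10 the real 13 in MIR75 (highest other 11) and 2 of 10 the real 17 in MIR77 (highest other 19). The other splits gave medians of 8, 8 and 12 lists in the comparisons of MIR73, MIR75 and MIR77 with N2. The number of lists called with the preset correlation is therefore weak evidence of a strain difference. For MIR77 against MIR73 and MIR75 together, 1 of 84 splits reached 2253 genes, the real split, and the next highest, 1882, was MIR73 against the rest.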

How the results depend on the processing

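RPKM recomputed from the counts, counts without the segment genes and the replicate blocks were alternatives chosen after seeing the data. The balance of genes higher and lower turned over in 3 comparisons: MIR75 against N2 (605 and 772 with recomputed RPKM), MIR75 against MIR73 (1353 and 2681 with recomputed RPKM, and also with both versions of the deposited RPKM) and MIR77 against the mean (2365 and 2567 with DESeq2). Of 136 named gene values, 134 kept their direction and side of the threshold under the alternatives run on single genes, which were the size factors, the DESeq2 test, no filter, only the strains compared and each library left out, but not RPKM; rol-6 and myo-2 in MIR77 did not, but none of the 136 changed sign. Genes named only in the observations, and most differences between MIR75 and MIR73, were not run under the alternatives. Of the 23 other values reported, 3 were kept throughout. The DESeq2 size factors kept 901, 1121, 3254, 2643 and 5154 of the calls of the 5 comparisons in the order of the report, and the DESeq2 test 849, 1041, 2909, 2375 and 4621. The labels carry no replicate numbers, but the records of N2, MIR73 and MIR77 alternate. With a replicate block by record order in N2 and MIR73, 221 genes were higher and 762 lower in MIR73 and 10 lists were called, 3 with an estimated correlation; beyond the 3 lists given in the report it changed no call of a list, a named gene, prdh-1 or alh-13 in MIR73. With the block in N2, MIR73 and MIR77, 204 genes were higher and 742 lower in MIR73 and 2049 and 1424 in MIR77, and no call of prdh-1 or alh-13 changed. Of the 3 pairs of N2 and MIR77 1 was correlated over 0.1, so the order was not taken as a pairing there; over the 3 strains, 8 of 9 libraries had their highest correlation with a library of their own number, and MIR77 replicate 3 did not.

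The DESeq2 test, run on all genes with a count, called prdh-1 in MIR73 (0.34, adjusted p = 0.044). Without a low-count filter, which took the prior degrees of freedom from 6.40 to infinity, prdh-1 in MIR73 (0.33, adjusted p = 0.017), alh-13 in MIR73 (0.48, adjusted p = 8.6e-08) and alh-13 in MIR75 (0.48, adjusted p = 7.6e-08) were called. Genes higher in MIR73 were then 321, genes lower in MIR75 719, lists called in MIR73 13, and shared genes 301 (MIR73 and MIR75), 276 (MIR73 and MIR77), 756 (MIR75 and MIR77) and 126 (all 3). Fitting only the strains compared called prdh-1 (0.34, adjusted p = 0.042) and alh-13 (0.48, adjusted p = 0.0098) in MIR73, with 252 genes lower in MIR75 and 589 lower in MIR75 than in MIR73. With an estimated correlation 4, 2 and 3 lists were called in MIR73, MIR75 and MIR77. The deposited RPKM gave, with a pseudocount of 0.1, 113 higher and 271 lower in MIR73, 186 and 91 in MIR75, 589 and 35 in MIR77, 480 and 725 in MIR75 against MIR73, and 922 and 139 in MIR77 against their mean. With a pseudocount of 1 these were 98 and 201, 168 and 72, 666 and 36, 436 and 657, and 944 and 147. RPKM recomputed from the counts gave 277 higher in MIR73, 772 lower in MIR75 and 2681 lower in MIR75 than in MIR73. The causes were not tested. Without the segment genes, 494 were higher and 383 lower in MIR75.

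Leaving out 1 library gave 95 to 148 higher and 576 to 681 lower in MIR73, 543 to 852 and 257 to 608 in MIR75, 997 to 1899 and 317 to 1687 in MIR77, 1282 to 1738 and 619 to 1232 in MIR75 against MIR73, and 1947 to 3544 and 959 to 2587 in MIR77 against the mean. Lists called were 8 to 11, 11 to 15 and 18 to 19. Shared genes were 118 to 185 (MIR73 and MIR75), 81 to 147 (MIR73 and MIR77), 195 to 500 (MIR75 and MIR77) and 43 to 76 (all 3). Depth limits genes with few counts: 14461 of 26159 genes with a count were tested.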

Other observations

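In this part, the tests of aex-5 for construct reads and for its neighbourhood, and the genes named at the tip of chromosome II, beside prdh-1 and on chromosome I, were chosen only after the result was seen.

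Several fixed lists not described so far were not called in any strain against N2. Of 15 genes raised by DAF-16, 1 rose and 1 fell in MIR73, 1 and 5 in MIR75, and 3 and 0 in MIR77 (2 and 2, 2 and 5, and 4 and 0 when adjusted over the list alone; camera adjusted p = 0.13, adjusted p = 0.086 and adjusted p = 0.41). Of 20 stress and lifespan regulators, 0 rose in any strain, and 1 fell in MIR73, 0 in MIR75 and 3 in MIR77 (1, 0 and 1 when adjusted over the list alone; adjusted p = 0.38, adjusted p = 0.49 and adjusted p = 0.079). Of 11 genes of the mitochondrial unfolded protein response, 2 fell in MIR77, and of 16 of the endoplasmic reticulum response, 1 fell in MIR77, likewise when adjusted over the list alone, with 0 other calls (lowest adjusted p = 0.13 and adjusted p = 0.079, both in MIR77). Nuclear-coded respiratory chain genes, 37 in all, gave 0 calls in MIR73, 1 rise in MIR75 and 2 in MIR77 (0, 1 and 0 when adjusted over the list alone; adjusted p = 0.068, adjusted p = 0.83 and adjusted p = 0.21). The median, mean and test of the DAF-16 list in MIR73 (0.02, -0.02, downward) and of the respiratory chain in MIR75 (-0.01, 0.02, upward) differed in sign.

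Several genes changed sharply beside genes that did not. At the left tip of chromosome II in MIR73, 2L52.1 changed by -4.44 ± 0.18 (SE, n = 3) and C01B12.9, which lies within it, by -4.81 ± 0.38. The next gene, the organic solute transporter osta-1 (6657 to 9484), changed by 3.72 ± 0.19, and best-4, a bestrophin gene that overlaps osta-1 (9444 to 11883), by 2.37 ± 0.23. In MIR75 the values were -0.26, -0.21, -0.03 and -0.15. B0513.4, a neighbour of prdh-1 on chromosome IV (13880151 to 13881546), was at 176 ± 2.1 CPM in N2 (SD, n = 3) and 61.0 ± 4.7 in MIR73, with 164 ± 3.6 in MIR75 and 188 ± 5.0 in MIR77. On chromosome I the adjacent genes tag-344, fbxa-125 (10646478 to 10647841) and B0511.11 (10648600 to 10654237) were lower in all 3 strains. The changes of fbxa-125 were -2.83, -4.55 and -3.26 in MIR73, MIR75 and MIR77.

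As a hypothesis, reads of the transgenes may have been counted to aex-5, because common GFP vectors end in the 3' region of unc-54, which lies 73 bp from aex-5 on the same strand. If so, the aex-5 changes would follow those of a transgene marker over the strains, but they lay in the order of the unc-119 changes in 2 of 3 pairs of strains, with MIR73 and MIR75 exchanged, which does not decide it. A change in dosage of the neighbourhood would raise the 8 nearest tested genes, whose median log2 change in MIR77 was 0.37, with a range of -0.14 to 2.79. A change of the aex genes as a group would raise the 5 other tested aex genes, whose median was 0.14. No read positions were analysed here, and the vectors are not given in the sources used here.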
